A study of Mus musculus with 16 samples.

How the data were processed

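Poly(A) RNA from splenic B cells of NOD.LT mice was made into stranded libraries and sequenced, with 4 libraries for each of 4 diets (NP, HAMS, HAMSA and HAMSB). The B cells came from magnetic negative selection, so other spleen cells that escape the antibodies remain in the libraries. The labels state 4 samples a diet and, in the same text, triplicates, and 4 libraries a diet are analysed. The replicate numbers are those of the labels (NP 1, 3, 4 and 5; HAMS 1, 4, 5 and 6; HAMSA 1, 2, 3 and 6; HAMSB 1, 2, 5 and 6), and the labels do not say which animals they stand for. The p-values therefore measure the spread between these libraries.

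Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts of the Subread package, and edgeR and limma were used (versions not given in the sources used here). The genome build and annotation release are also not given in the sources used here. The table the authors deposited holds a count of reads for each gene and library, unscaled, for 39179 genes, and was made for reverse-stranded libraries. The sum of each column equals the class of assigned reads in the deposited counting summary. Reads that map to several places, fall on overlapping genes, lie outside annotated exons or do not map are left out. This lowers the counts of genes with near-identical copies, such as Hspa1a and Hspa1b, the globin genes, H2 genes and immunoglobulin genes, and reads from NOD alleles that differ from the reference strain may be lost too. Of the gene identifiers, 37607 were matched to GENCODE M21 (GRCm38), which gave the coordinates printed and may not be the authors' annotation.

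Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter with a minimum count of 10 (15021 genes), libraries were scaled by TMM, and a negative binomial model with 1 mean per diet was fitted to all 16 libraries (12 residual degrees of freedom). Each pair of diets was compared with the quasi-likelihood F-test, and a further test asked for any difference among the diets. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with 0.05 as the threshold. Log2 fold changes carry the SE from the model, and CPM are means with the SD of 4 libraries. HAMSA against HAMS, HAMSB against HAMS and HAMSA against HAMSB were the main comparisons and the 3 against NP the secondary ones. The variation between libraries of a diet was 22.1%, and the median SE of a log2 fold change was 0.18 in each comparison of diets. HAMSA libraries were the shallowest, with 15053965 to 30723337 counts against 31707731 to 46206200 in the other diets. Measures of the libraries were compared with an exact permutation test, whose smallest p for 4 against 4 is 0.0286.

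The 45 gene lists cover B cell states, signalling, metabolism, stress responses and the other cells a spleen preparation can hold. They were written, with 14 single genes, the comparisons, the rule for named genes and a first set of other settings, before the data were examined. Of the identifiers in the lists 7 had no match (Ighd, H2-L, H2-Ea, P2ry8, Hbb-b1, Hbb-b2 and Ahsp) and were not analysed here. Lists with at least 3 measured members (44) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, and beside it with the correlation estimated from the data and with fry. Counts called "adjusted over the list alone" use the Benjamini-Hochberg method over the members of that list.

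Genes named in the text follow a rule. They passed the test, had CPM that did not overlap between the 4 libraries of either diet, and had an average log2 CPM of at least 1. Immunoglobulin V, D and J segments, genes with clone or model numbers for names, and pseudogenes were left out. The 12 largest rises and 12 largest falls of each main comparison and 5 of each in a secondary one were taken, filled up to 5 by the smallest p where fewer passed. For each called list up to 4 members with the smallest p were added. The table holds 253 duplicated symbols, and genes were told apart by their identifiers.

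The gene and list tests were run on simulated data with 200 changed genes in each of the 6 comparisons. The changed genes averaged at least 1 CPM. At a true fold of 2, between 62.7% and 76.1% of changed genes were called, at a fold of 4 between 92.4% and 98.5%, and 3 to 12 unchanged genes were called. The raised list was called each time, and 1 of 40 unchanged lists was called in HAMSB against NP and 0 in the others. The simulated genes varied independently, the unchanged lists were random genes, and no structure by replicate number was included. The run therefore does not show how often lists of genes that vary together are called without a change.

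The settings chosen beforehand were DESeq2 1.42.0, limma voom, RLE scaling, library totals without TMM, no filter, a filter of 1 CPM in 4 libraries, only the 2 diets compared, immunoglobulin genes left out, robust dispersion, a block for the replicate number and each library left out in turn. Added after the data were seen were all libraries thinned to 15053965 counts, the share of reads outside exons as a covariate, a term for replicate numbers 1 to 4 against 5 and 6, each of these sets alone, and the HAMS libraries split between HAMS against NP and HAMS against HAMSB. Within a diet, a library was singled out by Dixon's test at 95% confidence. No reads were available for realignment, so alignment and counting stand as the authors made them.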

Results

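Poly(A) RNA of splenic B cells was sequenced from NOD.LT mice, a strain of the non-obese diabetic mouse, which develops autoimmune diabetes. The mice were 15 weeks old and had eaten 1 of 4 diets for 5 weeks. The diets were NP, taken here as the diet without added resistant starch, and diets with such starch. HAMS holds high-amylose maize starch, the starch of HAMSA carries acetate, and the starch of HAMSB carries butyrate. Resistant starch passes to the colon, where bacteria ferment it and free the esterified acid. The B cells came from a negative selection, in which antibodies bind the other spleen cells and columns hold them back. Each diet had 4 libraries, named here by diet and by the number in the labels, and the labels do not say which libraries came from which animals. The question that the diets pose is whether starch, and acetate or butyrate released from it, changes the B cell transcriptome.

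The gene counts of NP libraries 1, 3, 4 and 5 summed to 31707731, 39161356, 35873569 and 42752976. HAMS libraries 1, 4, 5 and 6 held 37929476, 33434252, 35305082 and 31826691, and HAMSA libraries 1, 2, 3 and 6 held 30723337, 17453528, 15053965 and 16184519. HAMSB libraries 1, 2, 5 and 6 held 38714310, 42365411, 34720317 and 46206200. Every HAMSA library was thus shallower than every library of the other diets (n = 4 per diet; exact permutation p = 0.0286 against each diet, the smallest that 4 against 4 allows, and adjusted p = 0.152 over 48 such tests). HAMSA libraries also had the smallest mean share of reads outside annotated exons, 11.3% ± 1.09 (SD, n = 4), against 14.8% ± 0.667 in NP, 13.8% ± 2.25 in HAMS and 14.7% ± 1.93 in HAMSB. A total of 15021 genes passed the count filter, and the variation between libraries of 1 diet was 22.1% of a gene's level. Genes for other spleen cells were measurable in every library and differed between diets. The values are therefore those of a mixture, and in which cells a gene changed was not tested. In the first principal component, which held 31.1% of the variance, the 6 libraries numbered 5 and 6 ranged from −44.9 to 1.07 and the 10 numbered 1 to 4 from −20.1 to 64.9, so values within these numbers are given beside the results.

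**Figure D1:**
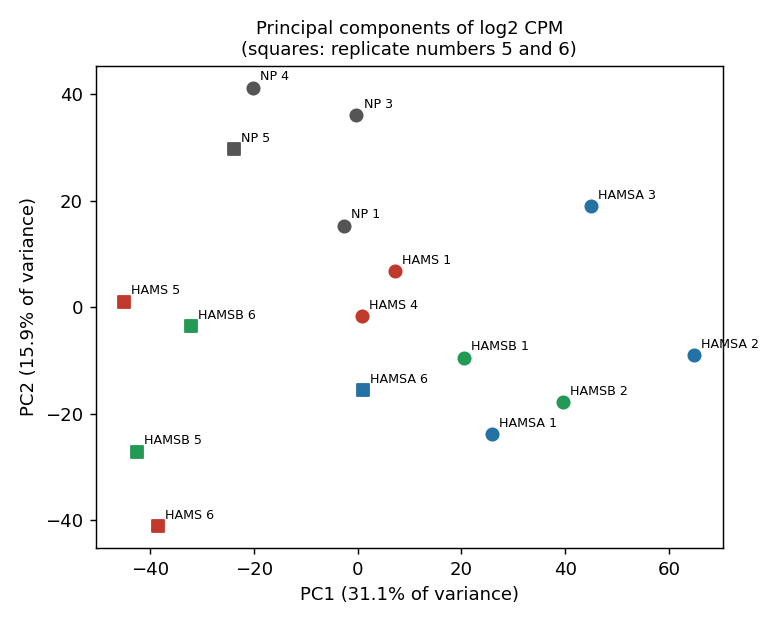
Principal components of log2 CPM of the 16 libraries. The x axis (31.1% of the variance) and the y axis (15.9%) are in arbitrary units, each point is a library, colour gives the diet, and squares mark libraries numbered 5 and 6, whose x values range from −44.9 to 1.07.

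Butyrylated starch was set against plain high-amylose starch to ask what butyrate adds. In HAMSB libraries, heat shock genes and some immediate early and unfolded protein response genes were lower than in HAMS libraries, and genes such as Gpr155, Slamf7 and Bcl6 were higher. Hspa1b, an inducible HSP70 chaperone, stood at 0.591 ± 0.183 CPM (counts scaled to the library total; SD, n = 4) against 15.6 ± 11.9, a log2 fold change of −4.71 ± 0.91 (SE). Sik1, a salt-inducible kinase, stood at 53.1 ± 1.11 against 345 ± 58.2 CPM (−2.70 ± 0.31), and Ddit4, an inhibitor of the mTORC1 growth pathway, at 56.9 ± 11.7 against 270 ± 11.8 CPM (−2.25 ± 0.25). Gpr155, a lysosomal membrane protein that senses cholesterol, was higher, at 30.5 ± 3.82 against 12.7 ± 1.79 CPM (1.26 ± 0.12). For each of these genes all 4 HAMSB libraries lay on the same side of all 4 HAMS libraries, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0127, 0.000356, 0.000312 and 0.000134. That separation is part of the rule for naming genes and no further evidence. Of all 15021 genes 7.30% had it, where chance gives 2.86%.

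Of 20 heat shock genes, 15 fell and none rose in HAMSB against HAMS, and 20 fell when adjusted over the list alone (median log2 fold change −1.22). Dnaja1, an HSP40 co-chaperone (−1.93 ± 0.31), Hspa8, the constitutive HSP70 (−1.17 ± 0.20), and Hspd1, the mitochondrial HSP60 (−1.16 ± 0.19), were among them. Of 25 immediate early genes, which cells switch on within minutes of a stimulus, 9 fell (12 lower and 1 higher adjusted over the list alone). Among these were the phosphatase gene Dusp1 (−2.27 ± 0.25), the transcription factor genes Crem (−2.10 ± 0.31) and Nr4a1 (−1.28 ± 0.19), and Ier2 (−0.98 ± 0.12). Genes of the unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, fell in 6 of 26 cases and in 14 adjusted over the list alone, among them Herpud1 (−0.60 ± 0.09) and Ddit3, the transcription factor CHOP (−0.67 ± 0.11). Of 13 glucocorticoid response genes, 5 fell (7 lower and 1 higher adjusted over the list alone), including Tsc22d3, the glucocorticoid-induced leucine zipper (−2.01 ± 0.26). Camera, a test of a list against all other genes, gave these 4 lists adjusted p = 2.13e-38, 8.03e-14, 1.08e-12 and 4.88e-11. The same test gave adjusted p = 0.0352, 0.0343, 0.0352 and 0.0352 with an estimated correlation. The heat shock score of HAMSB 5, 4.79, lay below the 5.05 to 5.09 of the other HAMSB libraries. Heat shock and immediate early genes also respond to the handling of cells, which the labels do not describe per library.

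**Figure D2:**
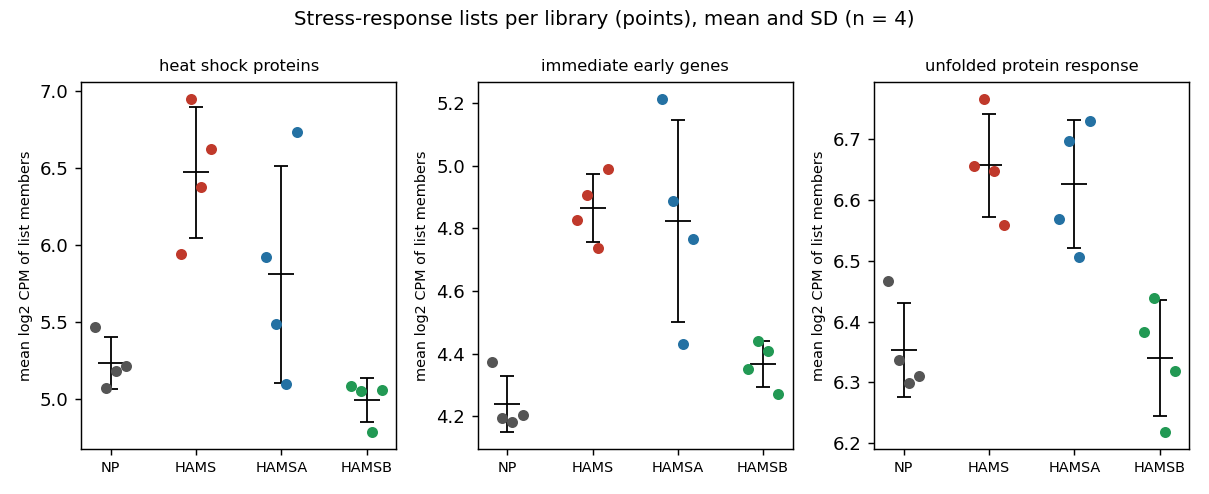
Mean log2 CPM of the heat shock, immediate early and unfolded protein response lists (y axis) in each library (points) by diet (x axis), with mean and SD of 4 libraries. The heat shock score is 6.47 ± 0.422 in HAMS, 5.81 ± 0.701 in HAMSA, 5.24 ± 0.168 in NP and 5.00 ± 0.141 in HAMSB.

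Among the genes that rose in HAMSB against HAMS, Slamf7 (1.20 ± 0.13) and Slamf1 (0.95 ± 0.12) belong to the SLAM receptor family, and Cd180 (0.99 ± 0.14) is a Toll-like receptor homologue of B cells. Bcl6, the transcriptional repressor of germinal centre B cells, stood at 154 ± 31.9 against 81.7 ± 17.4 CPM (0.92 ± 0.16), and Bcor, which encodes its corepressor, rose by 0.90 ± 0.11. Swap70, a signalling protein of activated B cells, doubled in CPM from 358 ± 42.6 to 708 ± 92.7 (0.98 ± 0.14). Il12a, a subunit of interleukin 12, stood at 19.2 ± 3.26 against 11.2 ± 0.753 CPM (0.78 ± 0.13), and Stat2, of interferon signalling, rose by 0.48 ± 0.09. Among genes that fell were Cebpb, a transcription factor of the acute response (−2.93 ± 0.40), and Cxcr4, a chemokine receptor (−1.72 ± 0.28). Sc5d (−0.99 ± 0.15) and Cyp51 (−0.58 ± 0.14) of sterol synthesis fell too. The cholesterol synthesis list had 2 of 23 genes lower, also adjusted over the list alone (camera adjusted p = 0.00049, adjusted p = 0.182 with an estimated correlation), and Cyp51 kept its call in 2 of 8 omissions of a library (highest adjusted p = 0.140, without HAMS 4).

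Regulatory B cell genes had 1 of 13 members higher, Il12a (4 adjusted over the list alone; camera adjusted p = 0.0028, adjusted p = 0.276 with an estimated correlation). Type I interferon genes had 1 of 35 higher, Stat2 (1 adjusted over the list alone; median 0.33, camera adjusted p = 0.0028, adjusted p = 0.672 with an estimated correlation). This call ended without HAMSB 2, where the mean of the list moved from 0.37 to −0.19 (adjusted p = 0.487). Ribosomal protein genes were lower in 78 of 79 cases (median −0.31, camera adjusted p = 4.88e-11, adjusted p = 0.496 with an estimated correlation) and nuclear genes of oxidative phosphorylation in 69 of 72 (−0.29, 4.61e-08, and adjusted p = 0.606 with an estimated correlation), with no member past the test in either list. Markers of other cells were higher in HAMSB beside these changes. Erythroid genes had a median of 2.93 (19 of 20 adjusted over the list alone; camera adjusted p = 1.72e-07), NK cell genes 1.57 (6 of 14; 7.76e-06), neutrophil genes 1.47 (none of 16; 9.4e-08) and T cell genes 1.41 (none of 22; 5.34e-09), all with adjusted p of 0.495 or 0.496 with an estimated correlation. Platelet genes were lower (median −0.80, adjusted p = 1.17e-07, and adjusted p = 0.495 with an estimated correlation). None of these markers passed over all genes, and the macrophage list was not called (median 0.34, adjusted p = 0.0704).

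Other B cell lists were called with few or no members past the test in HAMSB against HAMS. Transitional B cell markers had 1 of 11 higher, Tifa, an adaptor of NF-κB signalling (0.64 ± 0.12; 1 adjusted over the list alone; median 0.50, camera adjusted p = 0.0051, adjusted p = 0.495 with an estimated correlation), kept in 6 of 8 omissions (highest adjusted p = 0.0736, without HAMS 5). B-1 cell markers had none (1 higher and 1 lower adjusted over the list alone; median 0.36, 0.0337, adjusted p = 0.514 with an estimated correlation). Age-associated B cell markers, interferon gamma genes and cell cycle genes had none under either adjustment (medians 0.43, 0.23 and 0.36; 0.00727, 0.0051 and 0.00474; adjusted p = 0.495, 0.496 and 0.680 with an estimated correlation). These 4 lists were kept in 4, 7, 6 and 5 of 8 omissions, with the highest camera adjusted p without HAMSB 2 (0.306, 0.120, 0.260 and 0.780). The mean of the cell cycle list was 0.35, and 0.0446 to 0.53 over the omissions. Dendritic cell markers had none either (median 0.40, 0.0036, adjusted p = 0.583 with an estimated correlation) and were kept in 5 of 8 omissions (highest adjusted p = 0.156, without HAMS 6).

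In total 65 genes rose and 187 fell in HAMSB against HAMS, with a median change of 0.74 in size. With library totals in place of TMM scaling the split was 142 higher and 141 lower. Within numbers 1 to 4, with 2 libraries a diet, 74 genes were called, and within numbers 5 and 6, 101, with 136 when only these diets were fitted and 402 with the share of reads outside exons as a covariate. The count of 252 became 127 without HAMS 4, 157 without HAMS 6, 135 without HAMSB 1, 163 without HAMSB 5 and 144 without HAMSB 6, and 31 of the 39 named genes that passed did so in every omission. Hspa1b was an exception, with adjusted p = 0.0531 without HAMSB 1. On GRCm38 (GENCODE M21), Gpr155 lies on chromosome 2 from 73341506 to 73386572, Slamf7 on chromosome 1 from 171632403 to 171653035, and Sik1 and Hspa1b on chromosome 17 from 31844250 to 31855804 and from 34956436 to 34959238, all on the minus strand. Hspa1b and its near-identical neighbour Hspa1a share reads that the counting leaves out, so the level of each is uncertain.

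Acetylated starch was set against plain high-amylose starch to ask what acetate adds. No gene passed the test between HAMSA and HAMS libraries, and the values given here did not pass. Plaur, the urokinase receptor, stood at 144 ± 8.67 CPM in HAMSA against 227 ± 27.1 in HAMS (log2 fold change −0.66 ± 0.11, SE, n = 4 per diet). The immediate early genes Crem and Nr4a1 had lower means in HAMSA, with Crem at 20.7 ± 8.92 against 63 ± 26.1 CPM (−1.61 ± 0.31) and Nr4a1 at 47.2 ± 12.6 against 91.5 ± 23.2 CPM (−0.95 ± 0.18). HAMSA 6 alone held 33.9 CPM of Crem. Red cell genes had higher means, with Alas2, an enzyme of haem synthesis, at 108 ± 92.8 against 1.5 ± 1.18 CPM (6.17 ± 1.47) and the globin gene Hba-a1 at 1442 ± 1266 against 26.1 ± 14.5 CPM (5.79 ± 1.41). edgeR's quasi-likelihood test gave all of them adjusted p = 0.300, the smallest in this comparison.

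Heat shock genes were lower in HAMSA than in HAMS in 19 of 20 cases (median −0.54), with Chordc1, a co-chaperone of HSP90 (−0.70 ± 0.26), and Hspa8 (−0.49 ± 0.20) among them. No member passed over all genes or adjusted over the list alone, and camera gave adjusted p = 1.28e-08, or adjusted p = 0.384 with an estimated correlation. Within numbers 5 and 6, with 1 HAMSA library, the mean of the list was 0.23, where it was −0.53 over all libraries. Of 13 glucocorticoid response genes, 5 fell adjusted over the list alone, among them Ddit4 (−1.02 ± 0.24), though none over all genes (camera adjusted p = 0.013, adjusted p = 0.384 with an estimated correlation). That call ended without HAMS 6 (adjusted p = 0.071). Cell cycle genes had higher values in HAMSA for 40 of 40 members, such as Ube2c, which encodes a ubiquitin-conjugating enzyme of mitosis (1.66 ± 0.58), and Rrm2 of nucleotide synthesis (1.22 ± 0.44). Their median was 0.68 (camera adjusted p = 2.52e-14, adjusted p = 0.384 with an estimated correlation), with no member past either adjustment. HAMSA 2 held the highest cell cycle (5.05) and erythroid scores (6.33, mean log2 CPM) of all libraries, while HAMS 1 had 4.04 and 1.67. Whether B cells or red cell precursors carried the cell cycle genes was not tested. Transitional B cell markers, of cells newly arrived from the marrow, had a median of 0.40 (2 of 11 higher adjusted over the list alone; camera adjusted p = 0.00339, adjusted p = 0.384 with an estimated correlation). The list of short-chain fatty acid receptors and transporters had higher values for 6 of 7 members, none past either adjustment. Among them were the lactate and butyrate carrier gene Slc16a3 (1.05 ± 0.37) and the acetate receptor gene Ffar2 (0.68 ± 0.60). Its median was 0.68 (camera adjusted p = 0.0364, adjusted p = 0.384 with an estimated correlation), and it kept the call in 4 of 8 omissions (highest adjusted p = 0.103, without HAMS 4). Its mean was 0.66, and −0.19 within numbers 5 and 6.

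B-1 cell, age-associated and regulatory B cell markers had medians of 0.40, 0.39 and 0.34 in HAMSA against HAMS, with no member past either adjustment, among them the surface antigen gene Cd5 (1.05 ± 0.37). T cell markers had higher values in this comparison too, and whether the value of Cd5 came from B cells or T cells was not tested. Camera gave adjusted p = 0.0193, 0.00463 and 0.0364, each with adjusted p = 0.384 with an estimated correlation, and the B-1 and regulatory lists were kept in 7 and 5 of 8 omissions, with the highest adjusted p without HAMSA 1 (0.0535 and 0.163). Cholesterol synthesis genes had 1 of 23 lower adjusted over the list alone and none over all genes (median −0.14, 0.0364, adjusted p = 0.384 with an estimated correlation), kept in 4 of 8 omissions (highest adjusted p = 0.127, without HAMS 4). The 13 genes of the mitochondrial genome were all lower in value, none past either adjustment (median −0.32, 0.0196, adjusted p = 0.672 with an estimated correlation), kept in 4 of 8 omissions (highest adjusted p = 0.149, without HAMS 5). Nuclear genes of oxidative phosphorylation had a median of 0.12, none past either adjustment (0.0113, adjusted p = 0.910 with an estimated correlation). The mean of that list was 0.12 too, and −0.21 with the share of reads outside exons as a covariate, and the call was kept in 4 of 8 omissions (highest adjusted p = 0.603, without HAMSA 2).

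Beside these groups, erythroid markers were higher in HAMSA for all 20 members (median 4.05, 19 adjusted over the list alone, camera adjusted p = 1.27e-23, adjusted p = 0.384 with an estimated correlation). Neutrophil markers were higher for all 16 (median 2.00, 12 adjusted over the list alone, 4.09e-13), macrophage markers for 23 of 24 (0.92, 2 adjusted over the list alone, 1.43e-09), and NK and T cell markers for all members (1.48 and 1.20, none adjusted over the list alone, 1.23e-05 and 8.65e-09). Each of these had adjusted p = 0.384 with an estimated correlation as well. Dendritic cell markers had a median of 0.64 (6.11e-05, adjusted p = 0.384 with an estimated correlation) and platelet markers −0.64 (2.69e-05, adjusted p = 0.412 with an estimated correlation). With the share of reads outside exons as a covariate, 6 of the 18 list calls in this comparison were kept, 11 were lost and 1 turned direction. At an unadjusted p under 0.05, 1751 genes differed between HAMSA and HAMS, where chance gives 751. DESeq2 called 105 genes, limma voom 0, the quasi-likelihood test 11 within numbers 1 to 4 and 29 within numbers 5 and 6, where HAMSA has 1 library and other diets supply the spread. The count of 0 became 26 without HAMSA 6 and 3 without HAMS 1.

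HAMSA and HAMSB libraries were compared directly to ask whether acetate and butyrate differ. Pmepa1, a membrane protein that restrains TGF-β signalling, was higher in HAMSA, at 37 ± 3.52 against 14.6 ± 1.33 CPM (log2 fold change 1.34 ± 0.16, SE, n = 4 per diet). Cebpb stood at 25.7 ± 6.67 against 4.32 ± 0.777 CPM (2.57 ± 0.39) and Jund, an AP-1 transcription factor, at 335 ± 51.5 against 161 ± 10.4 CPM (1.05 ± 0.16). Gpr155 was lower in HAMSA, at 17.3 ± 1.35 against 30.5 ± 3.82 CPM (−0.82 ± 0.12), as was Cd55, which shields cells from complement, at 173 ± 42.3 against 324 ± 54.1 CPM (−0.91 ± 0.16). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.00388, 0.0111, 0.0111, 0.00912 and 0.0187. For each gene the 4 libraries of a diet lay apart from the 4 of the other, as the rule for naming genes requires. Of all genes 8.81% were apart in this way, where chance gives 2.86%. Pmepa1 lies on chromosome 2 of GRCm38, from 173224458 to 173276533, minus strand.

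Of 25 immediate early genes, 6 rose in HAMSA against HAMSB and 11 did so adjusted over the list alone, among them Ier5 (0.60 ± 0.08), Ier2 (0.73 ± 0.12) and Dusp2 (0.62 ± 0.10). Unfolded protein response genes rose in 4 of 26 cases, with 13 higher and 1 lower adjusted over the list alone, including Sdf2l1 (0.49 ± 0.09) and Creld2 (0.56 ± 0.11) of the endoplasmic reticulum. Camera gave these lists adjusted p = 6.74e-10 and 4.71e-08, and adjusted p = 0.147 and 0.307 with an estimated correlation. Of 13 glucocorticoid response genes, 3 rose (6 adjusted over the list alone), with Ddit4 at 1.23 ± 0.24 (camera adjusted p = 0.000339, adjusted p = 0.674 with an estimated correlation). Heat shock genes were higher in HAMSA for 20 of 20 members (median 0.71), 16 of them past the test adjusted over the list alone and none over all genes (3.16e-11, adjusted p = 0.674 with an estimated correlation). Hspa1b had a log2 fold change of 3.81 ± 0.89 (adjusted p = 0.0611), and the 4 HAMSA libraries spread from 0.599 to 24.6 CPM. Ribosomal protein genes were higher for 71 of 79 members (median 0.44) with Rps2 past the test (0.85 ± 0.17), and oxidative phosphorylation genes for 70 of 72 (0.39), each with 2 members past it adjusted over the list alone. Both lists had camera adjusted p = 2.79e-13 and adjusted p = 0.762 with an estimated correlation. With the share of reads outside exons as a covariate the mean of the oxidative phosphorylation list moved from 0.38 to −0.07.

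Genes that fell in HAMSA against HAMSB included Slamf7 (−0.78 ± 0.13), Slamf1 (−0.66 ± 0.12) and Bcor (−0.61 ± 0.11), 3 genes that rose in HAMSB against HAMS. Others were Il5ra, the interleukin 5 receptor of B-1 cells (−0.82 ± 0.17), and Stap1, an adaptor of B cell receptor signalling (−0.73 ± 0.14). Type I interferon genes had 1 of 35 lower, Stat2 (−0.42 ± 0.09; 4 adjusted over the list alone), and 31 of 35 with lower values. Their median was −0.47 (camera adjusted p = 5.63e-05, adjusted p = 0.762 with an estimated correlation). Their mean was −0.44, and 0.16 within numbers 5 and 6, and the call ended without HAMSB 2 (camera adjusted p = 0.498). HAMSB 2 had a type I interferon score (mean log2 CPM) of 5.57. The other HAMSB libraries had 4.00 to 4.36 and the HAMSA libraries 4.00 to 4.56. Interferon gamma genes had none past the test over all genes (4 lower and 1 higher adjusted over the list alone; median −0.26, camera adjusted p = 0.0325, adjusted p = 0.762 with an estimated correlation), kept in 6 of 8 omissions (highest adjusted p = 0.365, without HAMSB 2). HAMSB 2 held the highest interferon gamma score, 5.27, against 4.67 to 4.77 in the other HAMSB libraries. Erythroid markers (median 0.95, 5.63e-05), macrophage markers (0.56, 0.00153) and cell cycle genes (0.37, 0.000339) were higher in HAMSA, with no member past the test and adjusted p = 0.762, 0.762 and 0.796 with an estimated correlation. The macrophage call ended without HAMSB 6 (camera adjusted p = 0.0796). The cell cycle call was kept in 6 of 8 omissions (highest camera adjusted p = 0.264, without HAMSA 2), with list means from 0.07 to 0.69. With the exon covariate the means of the erythroid, macrophage and cell cycle lists moved from 1.24, 0.51 and 0.39 to −0.40, −0.40 and −0.31.

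In all, 88 genes rose and 29 fell in HAMSA against HAMSB. This count of 117 became 18 without HAMSA 2, 19 without HAMSA 3, 187 without HAMSA 6, 35 without HAMSB 1, 13 without HAMSB 5 and 27 without HAMSB 6. It was 10 within numbers 1 to 4, 4 when only these diets were fitted, 2 with a block for the replicate number and 0 with the exon covariate. That covariate does not overlap between HAMSA and HAMSB libraries, so the loss with it cannot be told apart from diet. Within numbers 5 and 6 HAMSA has 1 library and other diets supply the spread, and of 81 genes called there 8 are among the 117. Of the 34 named genes that passed, 7 did so in every omission, among them Pmepa1, Jund, Gpr155, Ier2 and Ier5. Cebpb was kept in 7 of 8 (0.055 without HAMSB 5), Slamf7 and Dusp2 in 5, Cd55, Bcor, Sdf2l1, Slamf1 and Ddit4 in 4, Rps2 in 3, Creld2 and Stap1 in 2, Il5ra in 1 and Stat2 in 0. The highest adjusted p among these genes was 0.147, for Stat2 without HAMSB 6.

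HAMSA and HAMSB effects relative to HAMS correlated across 15021 genes with Pearson's r = 0.662, where genes are not independent replicates. Both comparisons use the same HAMS libraries, and 40 simulations of unchanged groups against them gave a mean r of 0.485 and at most 0.521. The simulated genes varied independently, with no structure by replicate number or other cells. The simulated values are therefore no upper bound on what shared HAMS libraries alone give. The covariance was 0.169 against 0.0494 simulated, a difference of 0.120. Of all genes, 55.9% had the same sign, against 66.4% simulated. With the HAMS libraries split between the comparisons, r averaged 0.391 and ranged from 0.111 to 0.507 over 6 assignments. Over the 9586 genes with a log2 CPM of at least 3, r was 0.469, and no simulation was run for these genes. No gene was called in both, since HAMSA against HAMS had no call.

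**Figure D3:**
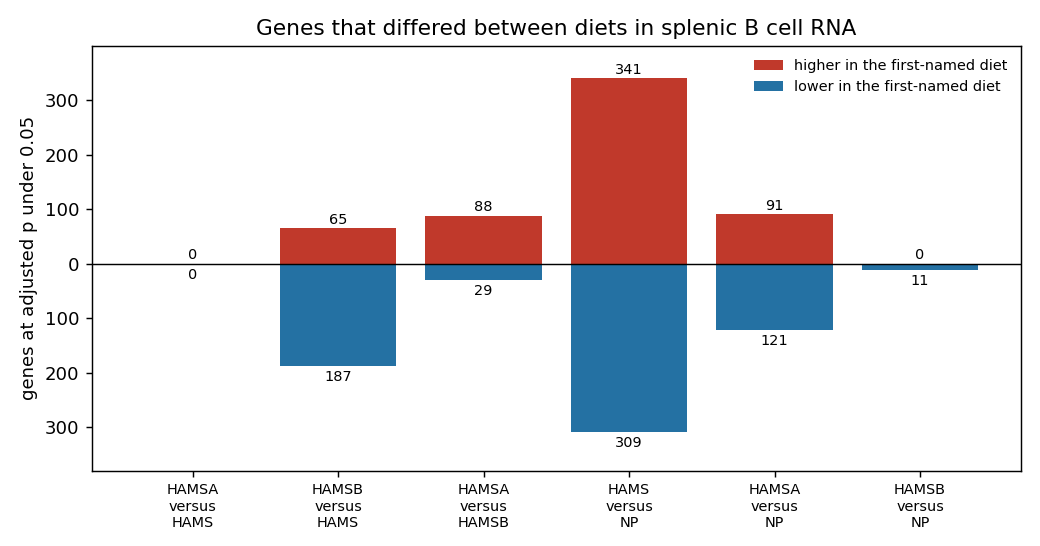
Genes that rose (upward bars) and fell (downward bars) at adjusted p under 0.05 in each of the 6 comparisons (x axis), by edgeR's quasi-likelihood test over 15021 genes. HAMS against NP had the most genes, 341 and 309, and HAMSA against HAMS had 0.

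Plain high-amylose starch was set against NP, taken as the diet without it. Other differences between these diets were not examined, so the values compare whole diets and not starch alone. Heat shock genes and some immediate early genes were higher in HAMS, and some macrophage markers were lower. Cd163, the haemoglobin scavenger receptor of macrophages, stood at 0.437 ± 0.197 CPM in HAMS against 9.35 ± 3.51 in NP (log2 fold change −4.39 ± 0.57, SE, n = 4 per diet), and Mrc1, their mannose receptor, at 1.39 ± 0.44 against 12.3 ± 5.17 CPM (−3.14 ± 0.42). Ier2 stood at 135 ± 21.1 against 58.6 ± 2.54 CPM (1.21 ± 0.12), and Nr4a1, an orphan nuclear receptor gene induced by antigen receptor signals, at 91.5 ± 23.2 against 31.4 ± 2.7 CPM (1.54 ± 0.19). Ccr7, which guides lymphocytes to T cell zones, stood at 256 ± 42.9 against 143 ± 13.2 CPM (0.84 ± 0.11). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.00105, 0.00111, 0.000335, 0.000762 and 0.00105, and all 5 genes passed in every omission of a library. On GRCm38, Cd163 lies on chromosome 6 from 124304656 to 124330527, plus strand, and Ier2 on chromosome 8 from 84661331 to 84662852, minus strand.

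Of 20 heat shock genes, 15 rose in HAMS against NP (17 adjusted over the list alone; median 1.19), among them Dnaja1 (2.02 ± 0.31), Dnajb1 (1.60 ± 0.30) and Hspd1 (1.23 ± 0.19). Hspa1b (3.75 ± 0.86) passed over all libraries and in 3 of 8 omissions (highest adjusted p = 0.0895, without NP 3). Of 25 immediate early genes, 8 rose (15 higher and 2 lower adjusted over the list alone), with Crem at 2.26 ± 0.32, Dusp1 at 1.85 ± 0.25 and Cd69, an early activation antigen, at 1.16 ± 0.16. The immediate early score of NP 1, 4.37, stood above the 4.18 to 4.21 of the other NP libraries. Unfolded protein response genes rose in 9 of 26 cases (11 adjusted over the list alone), with the stress kinase-like gene Trib3 at 0.83 ± 0.12, and 4 of 13 glucocorticoid response genes rose and 1 fell (5 and 1 adjusted over the list alone). Camera gave these lists adjusted p = 3.72e-21, 1.08e-13, 1.03e-08 and 0.000495. The estimated correlation kept only the immediate early list, with adjusted p = 0.154, 0.0366, 0.154 and 0.293 with an estimated correlation. Cholesterol synthesis genes rose in 2 of 23 cases (6 adjusted over the list alone), Sc5d (0.81 ± 0.15) and Cyp51 (0.74 ± 0.14), with camera adjusted p = 0.000124 and adjusted p = 0.154 with an estimated correlation.

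Of 24 macrophage and monocyte markers, 13 fell in HAMS against NP (16 lower and 1 higher adjusted over the list alone; median −2.02, camera adjusted p = 6.13e-20, adjusted p = 0.215 with an estimated correlation). The complement gene C1qc (−2.79 ± 0.49) was among them, while Lyz2, the most abundant marker, stood at 119 ± 44.5 against 170 ± 64.6 CPM. Erythroid markers had a median of −2.14 (18 of 20 with lower values, none past the test; 0.00154, adjusted p = 0.726 with an estimated correlation), with the call lost without NP 3 (adjusted p = 0.0556). T cell markers had a median of 1.15 (21 of 22 with higher values, none past the test; 0.0012, adjusted p = 0.726 with an estimated correlation), lost without HAMS 6 (adjusted p = 0.134). Dendritic cell markers had −0.41 (none past the test; 0.0242, adjusted p = 0.726 with an estimated correlation), kept in 5 of 8 omissions (highest adjusted p = 0.203, without NP 1). Chemotaxis and homing genes of B cells rose in 5 of 20 cases (also adjusted over the list alone; camera adjusted p = 0.00907, adjusted p = 0.293 with an estimated correlation), Ccr7, Cxcr4 (1.32 ± 0.27) and the gut-homing integrin gene Itgb7 (0.60 ± 0.13) among them, where Itgb7 was kept in 4 of 8 omissions (highest adjusted p = 0.0763) and Cxcr4 in 6 (0.0578). Age-associated B cell markers had 3 of 11 lower (also adjusted over the list alone; 0.00907, adjusted p = 0.400 with an estimated correlation), among them Apoe (−0.70 ± 0.17), which was kept in 3 of 8 omissions (highest adjusted p = 0.0981). Follicular markers had 2 of 12 higher (also adjusted over the list alone; median 0.12, 0.00907, adjusted p = 0.359 with an estimated correlation). Marginal zone markers had 1 of 16 lower (also adjusted over the list alone; median −0.26, 0.00907, adjusted p = 0.609 with an estimated correlation). HAMS 6 held the lowest marginal zone score, 6.40 against 7.14 to 7.28 in the other HAMS libraries, and without it the call was lost (adjusted p = 0.133). Toll-like receptor genes had 2 of 26 lower, among them Tlr8 (−1.78 ± 0.47; 4 lower and 1 higher adjusted over the list alone; 0.0397, adjusted p = 0.293 with an estimated correlation), and were kept in 3 of 8 omissions (highest adjusted p = 0.105). Tlr8 itself was kept in 1 of 8 (0.114). Whether Apoe and Tlr8 fell in B cells, or in other cells together with the macrophage markers, was not tested. Oxidative phosphorylation and ribosomal genes had medians of 0.23 and 0.22 with no member past the test (0.000165 and 0.00202, both adjusted p = 0.726 with an estimated correlation). These were lost without HAMS 4 (0.0504) and HAMS 1 (0.0695) and their means moved from 0.22 and 0.20 to −0.10 and −0.17 within numbers 5 and 6.

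In total 341 genes rose and 309 fell in HAMS against NP, and with library totals in place of TMM scaling 225 rose and 573 fell. Within numbers 1 to 4 there were 1250 calls, and within numbers 5 and 6, with 1 NP library, 37. The count of 650 became 235 without NP 3, 246 without NP 4, 403 without NP 5, 309 without HAMS 4 and 270 without HAMS 6, and 26 of the 39 named genes that passed did so in every omission. Of the calls in this comparison, 154 genes lower and 42 genes higher than in HAMS were shared by NP and HAMSB. Independent lists of these sizes would share 4.25 and 1.34, and simulated unchanged groups shared 0. Both comparisons use the same HAMS libraries, which raises sharing, and unchanged groups have little to share, so neither figure measures it fairly. With the HAMS libraries split, 19 to 83 calls were shared. These effects correlated with r = 0.531 (simulated mean 0.510, at most 0.537; covariance 0.129 against 0.0494, a difference of 0.0793), and r was 0.109 to 0.512 with the HAMS libraries split. The simulated genes varied independently here too. Of all genes, 78.4% had the same sign, against 67.0% simulated, and r was 0.749 over the 9586 genes with a log2 CPM of at least 3, for which no simulation was run.

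**Figure D4:**
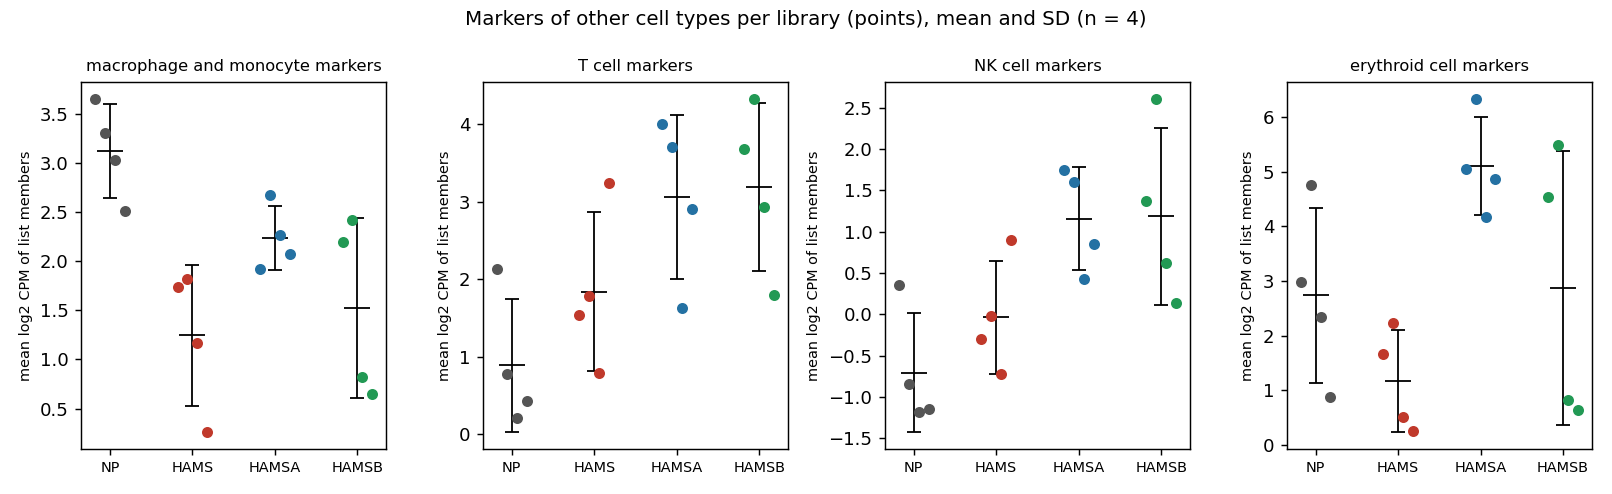
Mean log2 CPM of macrophage, T cell, NK cell and erythroid markers (y axis) in each library (points) by diet (x axis), with mean and SD of 4 libraries. The macrophage score is highest in NP (3.12 ± 0.481) and the erythroid score in HAMSA (5.11 ± 0.899).

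HAMSA, with starch and acetate together, was compared with NP, again as whole diets. Ier2 stood at 113 ± 4.91 CPM in HAMSA against 58.6 ± 2.54 in NP (log2 fold change 0.95 ± 0.12, SE, n = 4 per diet), Jund at 335 ± 51.5 against 162 ± 33.1 CPM (1.05 ± 0.16), and Klf2, a factor that governs lymphocyte quiescence and homing, at 407 ± 60.8 against 250 ± 38.8 CPM (0.70 ± 0.15). Fos stood at 13.9 ± 16 against 1.29 ± 0.241 CPM (3.43 ± 0.74), from 1.91 in HAMSA 6 to 36.4 in HAMSA 1. Mrc1 stood at 3.31 ± 1.09 against 12.3 ± 5.17 CPM (−1.90 ± 0.40), and Sema6d, a semaphorin, at 1.46 ± 0.23 against 4.61 ± 1.01 CPM (−1.65 ± 0.28). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.00787, 0.0211, 0.0381, 0.0395, 0.0381 and 0.0211.

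Of 25 immediate early genes, 8 rose in HAMSA against NP (14 adjusted over the list alone; median 0.59), Junb (0.84 ± 0.13) and Fosb (2.17 ± 0.46) among them, with camera adjusted p = 9.46e-11 and adjusted p = 0.105 with an estimated correlation. Unfolded protein response genes rose in 4 of 26 cases (11 higher and 1 lower adjusted over the list alone; 2.75e-06), with Herpud1 at 0.43 ± 0.09, and 1 of 20 heat shock genes rose, Hspd1 (0.80 ± 0.19; 9 adjusted over the list alone; 5.3e-06). Both lists had adjusted p = 0.583 with an estimated correlation. T cell markers had 1 of 22 higher, Lck, the T cell receptor kinase, at 93.5 ± 11 against 63.7 ± 2.07 CPM (0.55 ± 0.13). Adjusted over the list alone 21 were higher (median 2.28, camera adjusted p = 7.48e-14, adjusted p = 0.583 with an estimated correlation). Lck changed less than the list median and was kept in 1 of 8 omissions. In NP it lay above Lef1 and Tcf7, the next most abundant members, at 7.74 and 5.33 CPM, so it stands apart from the list. NK cell markers had 1 of 14 higher, Ncr1, an activating receptor (3.35 ± 0.78; 9 adjusted over the list alone; median 2.84, 3.85e-07), and neutrophil markers 1 of 16 (15 adjusted over the list alone; median 2.53, 1.41e-11), both with adjusted p = 0.583 with an estimated correlation. Macrophage markers had 2 of 24 lower, Mrc1 and Cd163 (10 lower and 1 higher adjusted over the list alone; median −1.21, 1.15e-05, adjusted p = 0.583 with an estimated correlation), and Lyz2 stood at 188 ± 54.6 against 170 ± 64.6 CPM. Erythroid markers (median 1.81, none past the test; 2.8e-07), cell cycle genes (0.74, 14 of 40 adjusted over the list alone; 4.01e-10) and oxidative phosphorylation genes (0.36, none past the test; 1.59e-09) were higher, each with adjusted p = 0.583 with an estimated correlation. Ribosomal genes had a median of 0.33 (none past the test; 8.43e-06, adjusted p = 0.675 with an estimated correlation). With the exon covariate the list means of erythroid, cell cycle, oxidative phosphorylation and ribosomal genes moved from 2.02, 0.78, 0.34 and 0.30 to −0.66, −0.06, −0.14 and −0.16. HAMSA and NP libraries do not overlap in that covariate, so its effect cannot be told apart from diet. Toll-like receptor genes had 1 of 26 lower (5 adjusted over the list alone; 0.0443), chemotaxis genes 2 of 20 higher, Ccr7 (0.60 ± 0.11) among them (4 adjusted over the list alone; 0.0443), and marginal zone markers none (2 of 16 lower adjusted over the list alone; median −0.30, 0.0362), each with adjusted p = 0.583 with an estimated correlation. These 3 lists were kept in 4, 4 and 6 of 8 omissions, with highest adjusted p = 0.0841, 0.164 and 0.0665.

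In total 91 genes rose and 121 fell in HAMSA against NP, and with library totals in place of TMM scaling 84 rose and 260 fell. The 212 calls became 4 without NP 3, 0 without NP 4, 3 without NP 5, 20 without HAMSA 1, 1 without HAMSA 2 and 589 without HAMSA 6, so without NP 4 each of the 24 named genes that passed missed the threshold, from adjusted p = 0.076 for Ier2 to 0.175 for Ctsw, the cathepsin W gene of T and NK cells. Ier2 was kept in 7 of 8 omissions, Jund and Junb in 5, and the other named genes in 1 to 4. With a block for the replicate number 0 genes were called. Within numbers 1 to 4 there were 2694 calls, within numbers 5 and 6, with 1 library of either diet and the spread from HAMS and HAMSB, 31, with the exon covariate 9 and with only these diets fitted 387.

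HAMSB, with starch and butyrate together, was compared with NP, again as whole diets. No gene rose and 11 fell. Cd163 stood at 0.876 ± 0.713 CPM in HAMSB against 9.35 ± 3.51 in NP (log2 fold change −3.42 ± 0.53, SE, n = 4 per diet), Mrc1 at 2.12 ± 1.12 against 12.3 ± 5.17 CPM (−2.54 ± 0.40) and C1qc at 2.06 ± 1.36 against 15.8 ± 3.48 CPM (−2.93 ± 0.49). Ddit4 stood at 56.9 ± 11.7 against 159 ± 49.3 CPM (−1.48 ± 0.24). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0303, 0.0307, 0.0409 and 0.039. Among genes that did not pass, Ncr1 stood at 3.25 ± 3.23 against 0.211 ± 0.212 CPM (3.97 ± 0.77, adjusted p = 0.0892), with 8.05 CPM in HAMSB 2, and Trac, the T cell receptor alpha constant gene, at 9.61 ± 7.15 against 0.922 ± 0.676 CPM (3.39 ± 0.84, adjusted p = 0.210).

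Of 24 macrophage and monocyte markers, 4 fell in HAMSB against NP (14 lower and 1 higher adjusted over the list alone; median −1.91, camera adjusted p = 1.01e-29, adjusted p = 0.155 with an estimated correlation). Lyz2 stood at 164 ± 93.9 against 170 ± 64.6 CPM. No T, NK or neutrophil marker passed over all genes, and 21 of 22, 11 of 14 and 14 of 16 were higher adjusted over the list alone (medians 2.69, 2.99 and 2.26; 2.3e-35, 1.2e-16 and 3.5e-19, each with adjusted p = 0.155 with an estimated correlation). Follicular markers had a median of 0.28, with 3 of 12 higher adjusted over the list alone (6.38e-05, adjusted p = 0.155 with an estimated correlation). Marginal zone markers had a median of −0.40 (14 of 16 with lower values, none past the test; 1.08e-05, adjusted p = 0.232 with an estimated correlation), among them Cr2, complement receptor 2 (−0.34 ± 0.16). HAMSB 5 held the lowest marginal zone score, 6.27, with 7.05 to 7.28 in the other HAMSB libraries and 7.37 to 7.48 in NP. Glucocorticoid response genes had 1 of 13 lower, Ddit4 (3 adjusted over the list alone; 0.00207, adjusted p = 0.343 with an estimated correlation), lost without NP 1 (adjusted p = 0.0786). Chemotaxis genes had 4 of 20 higher adjusted over the list alone and none over all genes (0.00361, adjusted p = 0.222 with an estimated correlation), with Ccr7 at 0.48 ± 0.11. Type I interferon genes were higher for 32 of 35 members, none past the test (median 0.37, camera adjusted p = 6.27e-07, adjusted p = 0.708 with an estimated correlation). They lost the call without HAMSB 2 (camera adjusted p = 0.707). HAMSB 2 had a list score (mean log2 CPM) of 5.57. The other HAMSB libraries had 4.00 to 4.36, within or below the 4.08 to 4.38 of NP. Cell cycle genes had a median of 0.38 (none past the test; 3.11e-05, adjusted p = 0.810 with an estimated correlation), lost without HAMSB 2 (0.481). Their mean was 0.39, with 0.09 to 0.57 when a library was left out, and −0.16 within numbers 5 and 6. Platelet markers (median −0.56, none past the test; 0.000161, adjusted p = 0.737 with an estimated correlation) had a mean of −0.51, and 0.89 within numbers 5 and 6 with 1 NP library, and NP 5 held the lowest NP score, 2.87 against 4.06 to 4.27.

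Circadian clock genes had 1 of 16 lower adjusted over the list alone, with Per3 at −0.59 ± 0.14, and none over all genes (median −0.14, camera adjusted p = 0.014, adjusted p = 0.171 with an estimated correlation). Costimulation genes had 1 of 18 higher adjusted over the list alone (median 0.13, 0.0415, adjusted p = 0.232 with an estimated correlation). Transitional markers (0.24, 0.0187), heat shock genes (−0.16, 0.0244) and ribosomal genes (−0.10, 0.00108) had none past either adjustment, with adjusted p = 0.655, 0.810 and 0.810 with an estimated correlation. In 8 omissions the circadian list was kept in 6, the transitional in 4, the costimulation in 1, the heat shock in 5 and the ribosomal in 6, with highest adjusted p = 0.108, 0.203, 0.124, 0.228 and 0.910, and the mean of the ribosomal list moved from −0.12 to 0.08 within numbers 1 to 4.

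The count of 11 became 0 without NP 1, NP 4, HAMSB 2 or HAMSB 5, 1 without NP 3 and 2 without HAMSB 6. None of the 5 named genes passed in every omission, with Cd163 kept in 3 of 8 and Mrc1, Ddit4 and C1qc in 2 (highest adjusted p from 0.129 to 0.140). Within numbers 1 to 4 there were 94 calls, within numbers 5 and 6, with 1 NP library, 1, with only these diets fitted 0 and with the exon covariate 43, and a test of any difference among the 4 diets called 568 genes.

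Genes fixed in advance for their links to short-chain fatty acids and B cell subsets passed in no comparison. Ffar2, a receptor for acetate, stood at 29.8 ± 3.87 CPM in NP, 14.6 ± 8.17 in HAMS, 23.5 ± 10.9 in HAMSA and 17.2 ± 11.3 in HAMSB (SD, n = 4). Niacr1, which encodes a butyrate and niacin receptor, came nearest, with a log2 fold change of −2.63 ± 0.78 in HAMS against NP (adjusted p = 0.0698). Ffar3, another receptor for these acids, lay at 0.777 ± 0.262 CPM in NP and at most 1.02 ± 0.724 in the other diets. Cd86, a costimulatory ligand, stood at 58.5 ± 8.16, 78.9 ± 21.8, 63.8 ± 2.62 and 65.2 ± 8.81 CPM in NP, HAMS, HAMSA and HAMSB. Cd80 had log2 fold changes from −0.33 to 0.13, and Il10, the regulatory cytokine gene, had means of at most 0.367 CPM. Ighm, the IgM heavy chain gene, stood at 10921 ± 850 CPM in NP, 12228 ± 3742 in HAMS, 15077 ± 1911 in HAMSA and 11137 ± 2018 in HAMSB. Cr2 stood at 2676 ± 235, 2067 ± 526, 1850 ± 251 and 2117 ± 293 CPM, with HAMSB 5 at 1683. Fcer2a, the follicular B cell gene for CD23, ranged in mean from 776 ± 114 in HAMSA to 1046 ± 258 CPM in HAMSB. The MHC class I genes B2m, H2-D1 and H2-K1 and the lipid-presenting gene Cd1d1 had log2 fold changes from −0.42 to 0.40. NOD alleles of H2 genes differ from those of the reference strain, so their absolute levels are uncertain.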

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

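The tests of heat shock genes and of other cells, and the counts over other splits of the libraries, were chosen after the results were seen, and so was the split into numbers 1 to 4 against 5 and 6, whose 3 tests were set before their values were seen.

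Heat shock genes were higher in HAMS than in the mean of NP and HAMSB (list median 1.20). Within numbers 1 to 4 and within 5 and 6, the latter with 1 NP library, the smaller and larger medians were 1.12 and 1.34, and with the share of reads outside exons as a covariate 1.21, which argues against unequal replicate numbers and that share as the cause. Fos, Fosb, Jun, Junb, Egr1 and Atf3, which respond to the handling of cells, had a median of 0.63 in the same contrast, with 0.94 for Fos and 0.05 for Egr1. The SE of this median, 0.18, is over the 6 genes and not between libraries. They belong to a list already seen to be higher in HAMS, and an effect of the diet on the cells would raise them too, so this value does not tell handling during isolation from diet. Both stay open, since any difference in handling is confounded with diet.

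In HAMSB against NP the macrophage markers had a median of −1.91 (SE 0.357) and the T cell markers 2.69 (SE 0.251). These SE are over the members of a list, which are not independent replicates. Between the 4 libraries of a diet the macrophage score had an SD of 0.481 in NP and 0.917 in HAMSB. The T cell score had an SD of 0.861 and 1.08. A lower share of all B cells alone would raise both medians. The pattern was chosen by the signs of these medians, so they are no separate test of that share. With a term for numbers 1 to 4 against 5 and 6 the medians were −1.86 and 2.74, against unequal replicate numbers. A different yield of each cell type in the negative selection, which removes both, was not tested and stays open, as does a change in the spleen itself. Lyz2, the most abundant macrophage marker, had 164 CPM in HAMSB and 170.0 in NP, and of the 22 T cell markers 2 are in another list.

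Libraries numbered 5 and 6 differed from those numbered 1 to 4 within diets by 1240 genes (512 higher and 728 lower; 6 against 10 libraries). Of 100 draws of the numbers within diets 2 gave as many genes, the real one included, with 1796 in the highest other draw. The split was chosen because the libraries were seen to part by it, so this count does not exclude chance. With the erythroid score as a covariate 0 genes were called by edgeR's test. Their median absolute log2 fold change moved from 0.53 to 0.46 while the median SE rose from 0.139 to 0.212. With the share of reads outside exons 0 genes were called too, with 0.54 moving to 0.31 and the SE from 0.139 to 0.178, so red cell precursors, that share and an unrecorded batch cannot be told apart.

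In 3 comparisons no other split of the libraries called as many genes as the diets. These were HAMSA against HAMSB (117 genes, 1 of 35 splits, highest other 0), HAMS against NP (650, 1 of 35, highest other 4) and HAMSA against NP (212, 1 of 35, highest other 0). For any diet 2 of 100 draws called as many (568 genes, highest other 4257). A share of 1 in 35 is the smallest possible, and the splits take no account of the replicate numbers, so they do not exclude chance. The counts of 117, 650, 212 and 568 depend on the setting. They were 141, 1044, 1531 and 1310 with a term for the numbers, and 0, 1157, 9 and 561 with the share of reads outside exons as a covariate. HAMSA libraries do not overlap with HAMSB or NP libraries in that share, so the 0 and 9 do not separate it from diet. With the block for the replicate number the counts were 2, 378, 0 and 264. With only the diets compared the first 3 were 4, 510 and 387, and without NP 4 HAMSA against NP had 0. Chance cannot be excluded for HAMSB against HAMS either (252 genes, 2 of 35), where the split of numbers 1 to 4 against 5 and 6 called 1997. With a term for these numbers 368 genes were called, and within them 74 and 101. Nor can it for HAMSB against NP (11; 2 of 35), where NP 1, NP 3, HAMSB 1 and HAMSB 2 against the rest called 17. In HAMSA against HAMS (0; 35 of 35) the split of HAMS 1, HAMS 4, HAMSA 2 and HAMSA 3 against the rest called 4557, which points to a structure of the libraries.

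Of 372 sets of 4 libraries of a diet, 21 had a library apart from the others by Dixon's test (1 of 40 library measures, 13 of 176 list scores and 7 of 156 genes), where chance gives about 1 in 20. HAMSA 1 had 30.7M counts, where the other HAMSA libraries had 15.1M to 17.5M. The mean share of unaligned reads was 6.7% in HAMSA (3.96% to 8.52%) and 6.20% in HAMSB (4.29% to 10.2%), where HAMS had 4.41% (3.73% to 5.32%) and the highest NP library 3.92%, and these reads were not analysed. NP 3 had 51.4 CPM of Alas2 and 507 CPM of Hba-a1. HAMSB 5 had 1683 CPM of Cr2 and 174 CPM of Hspa8, HAMSA 6 had 33.9 CPM of Crem, HAMSB 2 had 8.05 CPM of Ncr1 and NP 5 had 20.4 CPM of Slamf7.

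Among list scores (mean log2 CPM), NP 1 stood apart for Toll-like receptor (5.44), immediate early (4.37) and mast cell genes (0.82), and NP 5 for ribosomal (6.87) and platelet genes (2.87). HAMS 6 did so for acetyl-CoA (4.82) and marginal zone genes (6.40), and HAMSA 3 for chemotaxis (6.76), aryl hydrocarbon receptor (1.21) and cholesterol genes (3.99). HAMSA 6 stood apart for circadian genes (4.03), HAMSB 5 for heat shock genes (4.79) and HAMSB 2 for interferon gamma genes (5.27).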

How the results depend on the processing

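The tests with the term for replicate numbers, numbers 1 to 4 or 5 and 6 alone, thinning and the share of reads outside exons were chosen after the results were seen. Named genes passed the test 141 times over the comparisons, a gene counting once in each. Of these calls 141 were kept with DESeq2, 137 with RLE scaling, 137 with library totals, 125 with limma voom, 124 without a filter, 140 with the term, 93 within numbers 1 to 4, 86 with the exon covariate, 68 with the block and 38 within numbers 5 and 6, and 95 of 140 with only the diets compared. None changed sign in these settings. Within numbers 5 and 6 NP and HAMSA have 1 library each. The labels do not say whether the replicate numbers pair libraries across diets. Libraries with the same number correlated at −0.250 to 0.491 in their deviations from the diet means. No unmatched libraries were set beside these values, so pairing or a shared batch stays open. A block for the number was fitted only as another setting. The cause was not tested for any of the changes below.

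In HAMSA against HAMS, 0 genes became 105 with DESeq2, 11 within numbers 1 to 4, 29 within 5 and 6, 1 with the exon covariate, and 0 to 26 with a library left out. In HAMSB against HAMS, 252 became 608 with DESeq2, 136 with only these diets, 163 with the block, 402 with the exon covariate, 74 within numbers 1 to 4, 101 within 5 and 6, and 127 to 240.0 with a library left out. In HAMSA against HAMSB, 117 became 563 with DESeq2, 4 with only these diets, 2 with the block, 0 with the exon covariate, 10 within numbers 1 to 4, and 13 to 187 with a library left out.

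In HAMS against NP, 650 became 1258 with DESeq2, 378 with the block, 1157 with the exon covariate, 1044 with the term for the numbers, 1250 within numbers 1 to 4, 37 within 5 and 6, and 235 to 703 with a library left out. In HAMSA against NP, 212 became 1282 with DESeq2, 83 with limma voom, 344 with library totals, 75 without a filter, 387 with only these diets, 0 with the block, 9 with the exon covariate, 1531 with the term, 2694 within numbers 1 to 4, 31 within 5 and 6, and 0 to 589 with a library left out. In HAMSB against NP, 11 became 128 with DESeq2, 21 with limma voom, 7 with the CPM filter, 0 with only these diets, 5 with the block, 43 with the exon covariate, 51 with the term, 94 within numbers 1 to 4, 1 within 5 and 6, and 0 to 14 with a library left out. For any diet, 568 became 1879 with DESeq2, 264 with the block, 1310 with the term, 1266 within numbers 1 to 4, 109 within 5 and 6, and 259 to 705 with a library left out.

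Of 95 list calls, 5 passed with an estimated correlation and 19 with fry, and 88 to 104 lists were called with a library left out. These were not always the same lists. Of 760 tests of a called list with a library left out, 673 kept the call, 85 lost it and 2 turned direction. With the exon covariate 68 of the 95 calls were kept, 18 were lost and 9 turned. In HAMSA against HAMSB and HAMSA against NP the covariate does not overlap between the diets, so changes with it cannot be told apart from diet. The correlation of HAMSA and HAMSB effects relative to HAMS, r = 0.662, became 0.469 at a log2 CPM of at least 3, 0.391 with the HAMS libraries split, 0.565 with the block, and 0.457 to 0.732 with a library left out.

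Lists for which camera's direction turned follow, with the mean log2 fold change of the list. In HAMSA against HAMS, within numbers 5 and 6, short-chain fatty acid receptors were −0.19 and heat shock genes 0.23, and oxidative phosphorylation genes were −0.0205 with the block and −0.21 with the exon covariate, and 0.0150 within numbers 1 to 4. In HAMSB against HAMS, type I interferon genes (0.37 over all libraries) ranged from −0.19 without HAMSB 2 to 0.62 without HAMS 1. In HAMSA against HAMSB, type I interferon genes were 0.16 within 5 and 6, and with the exon covariate oxidative phosphorylation genes were −0.0727, cell cycle genes −0.31, macrophage markers −0.40 and erythroid markers −0.40. In HAMS against NP, within 5 and 6, oxidative phosphorylation genes were −0.10 and ribosomal genes −0.17. In HAMSA against NP, oxidative phosphorylation genes were −0.0251 within 5 and 6 and −0.14 with the exon covariate, ribosomal genes −0.16 and −0.16, and with the covariate cell cycle genes were −0.0642 and erythroid markers −0.66. In HAMSB against NP, ribosomal genes were 0.0793 within 1 to 4 and 0.0108 without HAMSB 5, and within 5 and 6 cell cycle genes were −0.16 and platelet markers 0.89.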

Other observations

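None of the tests in this part was planned beyond the list tests, and the values by replicate number were looked at after the libraries were seen to part by it.

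Of the 44 lists tested, 15 were called in no comparison. Nearest to the threshold were MHC class I genes in HAMS against NP (median log2 fold change 0.17, camera adjusted p = 0.0540), immunoglobulin constant regions in HAMSA against HAMSB (0.44, adjusted p = 0.0540), plasma cell genes in HAMSA against HAMS (0.14, adjusted p = 0.0559), mast cell markers in the same comparison (0.87, adjusted p = 0.0613) and glycolysis genes in HAMSB against HAMS (−0.12, adjusted p = 0.0633). Histone deacetylases, which butyrate inhibits, had values lower in HAMSA than in HAMSB for 17 of 20 members (−0.14, adjusted p = 0.120). The smallest adjusted p was 0.0866 for fatty acid oxidation (HAMSA against HAMS, 0.09), 0.130 for germinal centre genes (HAMSA against HAMSB, 0.45), 0.158 for aryl hydrocarbon receptor targets (HAMS against NP, −0.67) and 0.173 for spleen stroma (HAMSB against HAMS, 0.26). It was 0.192 for acetyl-CoA and fatty acid synthesis (HAMS against NP, 0.05), 0.285 for MHC class II (HAMSB against HAMS, −0.12), 0.298 for B cell receptor signalling (HAMSA against NP, −0.05), 0.332 for NF-κB targets (HAMSB against HAMS, 0.02, camera direction down) and 0.372 for apoptosis (HAMSB against HAMS, −0.04).

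Libraries numbered 5 and 6 had lower values of erythroid (median −2.53, 13 of 20 members lower), macrophage (−1.06, 14 of 24), cell cycle (−0.67, 20 of 40), dendritic cell (−0.58, 7 of 16) and oxidative phosphorylation genes (−0.32, 9 of 72) than libraries numbered 1 to 4 of the same diets. With an estimated correlation camera gave adjusted p = 0.452 for the erythroid, macrophage and dendritic cell lists and adjusted p = 0.589 for the other 2. Ccl5, a chemokine of T and NK cells (−1.06 ± 0.12, SE), and Car1, carbonic anhydrase of red cells (−2.95 ± 0.39), fell in edgeR's test. The labels do not say what the numbers stand for.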
